A study of Mus musculus with 8 samples.

How the data were processed

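Hippocampal RNA of C57BL/6 mice was sequenced in 8 libraries, which the labels place in 4 groups of 2: CRISPR knockouts of Pyk2 (KO), mice with the Y402F substitution in Pyk2 (Y402F), and wild-type controls of each line (KO controls and Y402F controls). Pyk2 is the tyrosine kinase encoded by Ptk2b, and tyrosine 402 is its autophosphorylation site. Per the labels' protocols, RNA was extracted with Trizol and libraries were built from total RNA. No label says whether a library holds 1 animal or a pool, or how the 2 libraries of a group relate, so p-values measure the spread between these libraries, which may be partly technical. The part of Ptk2b removed in the knockout is not given in the sources used here.

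The 2 kinds of library were processed differently by the submitters. The mutant tables deposited by the authors give, for each gene with a value above 0, an expected count, an FPKM value and a transcript length, with Entrez identifiers. Per the file headers, the authors' expected count is an estimate of the reads that come from a gene, with reads that fit several places divided between them; the processing notes do not name the program that made it. The control tables deposited by the authors give an FPKM value per Ensembl gene with a lower and an upper confidence bound, in the layout of Cufflinks, and no counts. Per the submitters' processing notes, Bowtie 1, HISAT and build mm9 apply to all 8 samples and Cufflinks to the controls. The gene positions in the control tables nevertheless lie on GRCm38, where 99.8% of 17705 genes share a start or an end with GENCODE M21; positions are given on that build. Since every mutant library came from one kind of table and every control library from the other, a difference of processing cannot be told from genotype in a comparison of a mutant with its controls. It does not enter the comparison of KO with Y402F or of the wild-type pairs, and it cancels in the difference of the mutant effects where it is the same in both lines.

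The expected counts of the mutant libraries summed to 5756180 and 5965760 (KO) and 5825060 and 6017220 (Y402F), and 81.1 to 81.7% of them were whole within 0.005. The FPKM of the control libraries summed to 3.25e+06 and 3.27e+06 (KO controls) and 2.61e+06 and 2.69e+06 (Y402F controls), against 384323 to 413544 in the mutant libraries, because the short noncoding RNA Bc1 and mitochondrially encoded genes took most of the control values. The number of reads in the control libraries is not given. The most frequent ratio between control libraries of values under 0.1 FPKM of the same gene lay within 0.5% of 1 for all 6 pairs, so 1 read was worth about the same in each of them. The confidence interval of Cufflinks reached a median of 26.7 to 29.7% above the value for genes near 10 FPKM, and covers the estimate of a single library only.

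Mutant genes were matched to control genes by symbol (17629) or by the Entrez table of GENCODE (89), 11 were dropped because of a repeated identity, and 17707 genes remained of the 18022 listed in any mutant library. Genes outside this set held 0.889 to 1.09% of the expected counts of the mutants and 51.9 to 62.0% of the FPKM of the controls. FPKM values were divided by median-of-ratios factors over genes at 1 FPKM or more in every library, and are called scaled FPKM. Before scaling the median gene was lower in the mutants by a log2 difference of -0.12 in both lines. Genes with a mean of at least 1 FPKM over the 8 libraries were tested (12974).

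The test was limma 3.58.1 with an intensity trend on log2(scaled FPKM + 1), with all 8 libraries in 4 groups and 4 residual degrees of freedom. Its log2 differences understate changes of genes with low values. For KO against Y402F, whose tables hold counts of one kind, the rule fixed beforehand called for the quasi-likelihood test of edgeR 4.0.16 on the expected counts, rounded to whole numbers, with TMM scaling, 12970 genes and 2 residual degrees of freedom; DESeq2 1.42.0 served as an alternative. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Lists of genes were tested with camera of limma at a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the 39 lists that could be tested. R 4.3.3, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.

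The comparisons, the lists, the alternatives and the rule for named genes were set before the data were examined. The rule names Ptk2b and its paralog Ptk2, the 10 largest rises and 10 largest falls among called genes whose libraries do not overlap between the groups (with no such condition for the difference of effects; symbols of the forms Gm and digits, Rik, LOC, AU, BC or AI and digits, Mir, Snor, Rn, mt-, Hist and -ps were left out), and up to 4 members of each list with the smallest p. Lists were discussed where camera called them or at least 2 members were called, and 5 lists were always reported. Of the list members the rule names, the text prints up to 4, and none for lists that camera did not call apart from those 5; that selection, and testing only the printed genes under the alternatives, was made after their values were seen, when the wider set had shown more changes of sign. Rny1, Mir8104 and A830082N09Rik fall outside the rule and were chosen after their values were seen. Alternatives covered the pseudocount, the scaling, the filter, the trend, the libraries in the fit, the replicate number as a block, and each library left out in turn. A term for sex, another size factor for the counts, limma for KO against Y402F and the leave-one-out list tests were added after seeing the data.

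The scripts were tested on simulated data. With 100 of 12956 genes changed by a log2 of 1 and 100 by a log2 of 2, edgeR recovered 89% and 100% for KO against Y402F, with 5 wrong calls. For the difference of effects limma recovered 82% and 100% over 12974 genes, with 8 wrong calls. It made 0 calls between simulated wild-type pairs with no gene changed. Each simulated gene had the common spread for edgeR, or the median spread at its level for limma, with no difference of sex or tissue. Only genes above a low level were changed. Recovery of genes that are low, or that vary more between these libraries, may therefore be lower. Genes that share reads with a near-identical copy or overlap another gene (clustered protocadherins, antisense transcripts, tubulins, glutathione transferases, ribosomal proteins with many pseudogenes, hemoglobins) are uncertain, because the counting may split their reads and no source states that it used strand.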

Results

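The study asked what loss of Pyk2, or of its autophosphorylation site alone, does to the mouse hippocampus in the setting of contextual fear memory. RNA-seq was available for 8 hippocampal libraries, 2 each of Pyk2 knockout mice (KO), Pyk2 Y402F mice (Y402F), wild-type KO controls and wild-type Y402F controls. The mutant libraries held between 5756180 and 6017220 expected counts; the depth of the control libraries is not given.

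Ptk2b, which encodes Pyk2 (Entrez 19229; chromosome 14, 66153257 to 66281052 on GRCm38), fell in the KO libraries and in no other group. Its level was 62.1 ± 8.88 scaled FPKM in KO (SD, n = 2), 373 ± 29.7 in Y402F, 307 ± 0.528 in KO controls and 319 ± 4.60 in Y402F controls. KO thus kept 20.2% of the level of its controls, with a log2 difference of -2.29 (SE 0.11, limma adjusted p = 2.41e-06). In Y402F the difference from its own controls was 0.22 (SE 0.11, limma adjusted p = 0.143), although quantile normalization gave 0.36 with an adjusted p of 0.0128 and a term for sex, added after seeing the data, 0.34 with 0.00738. The paralog Ptk2, which encodes focal adhesion kinase (chromosome 15), was at 20.9 ± 1.09 scaled FPKM in KO, 21.4 ± 0.318 in Y402F, 29.6 ± 6.97 in KO controls and 24.0 ± 3.79 in Y402F controls. Its differences from controls were -0.47 in KO (limma adjusted p = 0.0643) and -0.15 in Y402F (limma adjusted p = 0.530). The first passed without KO control replicate 2 (limma adjusted p = 0.0186), without scaling (0.0260) and with a replicate block (0.0330).

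**Figure D1:**
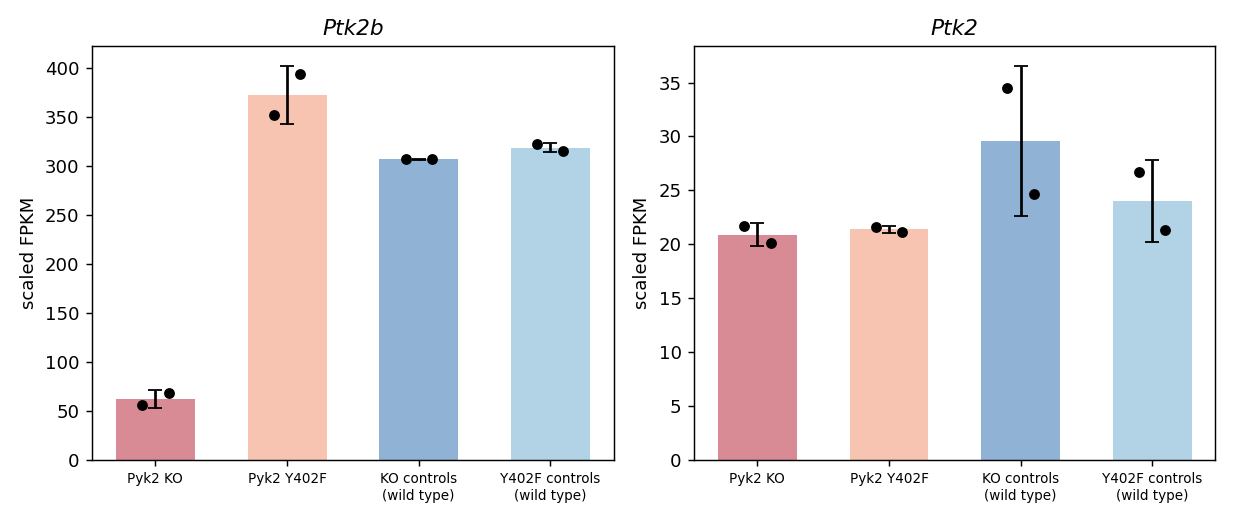
Scaled FPKM of Ptk2b and Ptk2 (y axes, from 0) in the 4 groups (x axis); dots are the 2 libraries of a group, bars their mean and lines the SD. Ptk2b lies at 55.8 and 68.4 in the KO libraries and between 307 and 394 in the other 6.

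Markers of sex and of choroid plexus set libraries apart within and between groups. Xist, which is expressed from the inactive X chromosome of females, was at 25.4 and 0.169 scaled FPKM in the KO libraries, and the Y-linked Ddx3y at 0.0417 and 5.05, so KO replicate 1 had a female and replicate 2 a male pattern. The Y402F libraries had the same split (Ddx3y 0.0422 and 4.72). Both KO controls had a female pattern (Xist 3.94 and 3.23, Ddx3y 0.0691 and 0.0692) and both Y402F controls a male one (Ddx3y 5.75 and 4.76). KO control replicate 2 also held 0.684 scaled FPKM of the Y-linked Eif2s3y, against 0 in replicate 1 and 7.83 or more in the Y402F controls. Ttr, the transthyretin gene that choroid plexus epithelium expresses strongly, was at 653 in Y402F replicate 2 and at 1011 and 1028 in the Y402F controls, against 1.19 to 10.2 in the other 5 libraries.

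**Figure D2:**
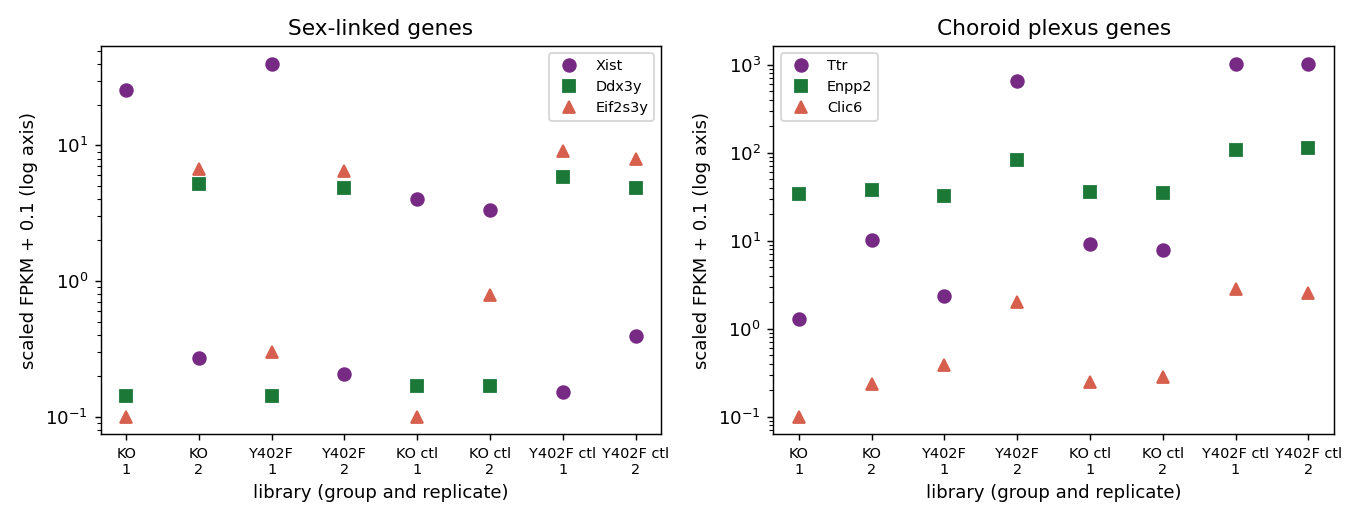
Scaled FPKM + 0.1 on a log axis of 3 sex-linked genes (left) and 3 choroid plexus genes (right) in each library (x axis; ctl, controls). Ttr, Enpp2 and Clic6 are highest in Y402F replicate 2 and in both Y402F controls.

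The comparison of KO with Y402F asks which transcripts depend on the Pyk2 protein beyond its autophosphorylation site, within tables made the same way. Ptk2b was the only gene called, at 16.7% of the Y402F level (log2 difference -2.59, SE 0.13, edgeR adjusted p = 4.41e-09). Of 12970 genes, 250 had an unadjusted p under 0.05. Tests with no true difference would on average give more, so few calls do not show that other genes are alike. DESeq2 called 2 genes. The second gene of DESeq2 was Npas4, an activity-dependent transcription factor, with 6.32 ± 2.89 scaled FPKM in KO and 1.65 ± 0.531 in Y402F (SD, n = 2). Its log2 difference was 1.94 (SE 0.32), with an adjusted p of 0.0954 in edgeR and 0.0204 in DESeq2. Npas4 was called by edgeR with another size factor (adjusted p = 0.0370) and without the symbol forms left out of the naming rule (0.0299). It was not called by edgeR with a replicate block (1.90, adjusted p = 0.143) or by limma (1.42, adjusted p = 0.864). Ptk2 did not differ detectably (-0.03, SE 0.14, edgeR adjusted p = 1). A term for sex, added after seeing the data, leaves 1 residual degree of freedom and gave 4 calls. Beside Ptk2b they were Ttr (-5.77, SE 0.36, edgeR adjusted p = 3.54e-05), Fmod (-2.04, SE 0.25, edgeR adjusted p = 0.0269) and Tmem181b-ps (0.90, SE 0.12, edgeR adjusted p = 0.0429). The last falls outside the naming rule and was chosen after its values were seen. With 1 library left out, edgeR called 16 genes without KO replicate 1, 17 without KO replicate 2, 34 without Y402F replicate 1 and 19 without Y402F replicate 2. These fits compare 1 library with 2, no longer balance the sexes, and assume that the lone library varies like the other group.

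Immediate early genes, which neurons switch on within minutes of activity, were higher in KO as a list. Of 26 members 24 had a positive log2 difference, with a median of 0.30 (camera adjusted p = 1.16e-19, adjusted p = 0.786 with an estimated correlation). Across all genes 0 members were called, and adjusted over the list alone 8 were, all higher. After Npas4 the smallest p-values belonged to Fos (1.35, SE 0.26), Fosb (1.29, SE 0.29) and Junb (0.73, SE 0.17), with edgeR adjusted p-values of 0.186, 0.569 and 0.573. Fos was at 10.1 ± 3.15 scaled FPKM in KO and 3.94 ± 0.155 in Y402F (SD, n = 2). This list was the only one of the 12 that camera called in this comparison whose call held without each of the 4 libraries in turn.

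**Figure D3:**
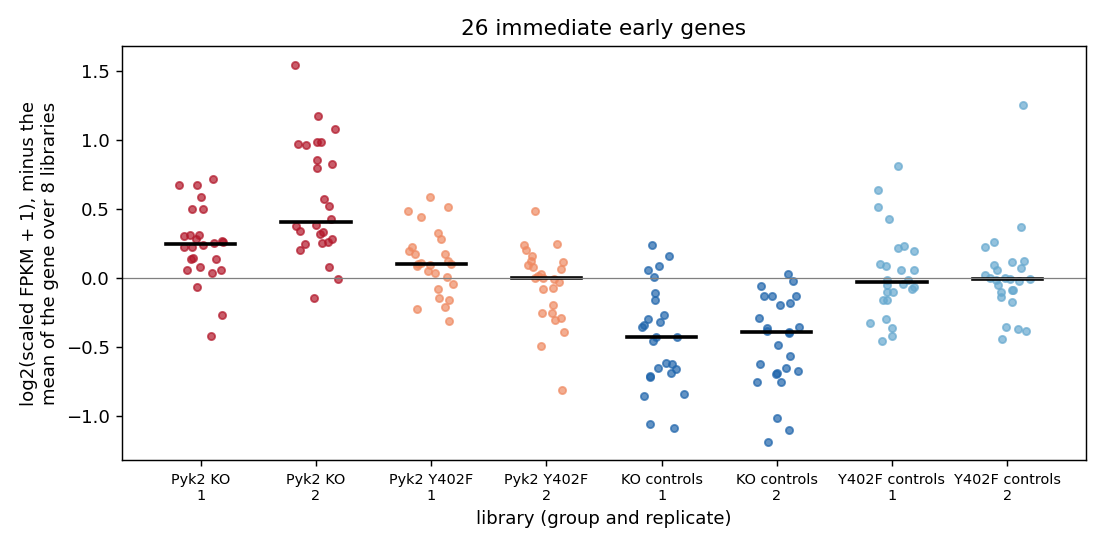
Immediate early genes in each library (x axis); each dot is 1 of 26 genes, as log2(scaled FPKM + 1) minus the mean of that gene over the 8 libraries (y axis), and black lines are medians. The KO libraries lie above the Y402F libraries, and the KO controls below the Y402F controls.

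Choroid plexus genes were lower in KO, with all 8 members negative and a median of -1.60 (camera adjusted p = 8.67e-12, adjusted p = 0.786 with an estimated correlation). Without the term for sex no member was called over all genes and 4 were adjusted over the list alone. Ttr differed by -5.84 (SE 1.29) and Enpp2, which encodes autotaxin, by -0.68 (SE 0.27). Without Y402F replicate 2 the direction of this list turned, with a camera adjusted p of 0.707. Genes of leptomeninges and fibroblasts were lower too (13 members, median -0.37, camera adjusted p = 4.43e-07, adjusted p = 0.786 with an estimated correlation), with 2 members lower when adjusted over the list alone and Fmod, a small collagen-binding proteoglycan, at -2.03 (SE 0.38). Their call was lost without Y402F replicate 2 (0.321) and narrowly without KO replicate 1 (0.0593). The dentate granule cell list was lower (12 members, median -0.24, camera adjusted p = 0.000346, adjusted p = 0.786 with an estimated correlation), with C1ql2 at -0.31 (SE 0.14) and the granule cell transcription factor Prox1 at -0.29 (SE 0.15). That call was lost without KO replicate 1 (0.124).

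Camera called 8 further lists. Higher in KO were blood genes (6 members, median 0.35, with the hemoglobin gene Hba-a2 at 1.37, SE 0.28, the 1 member that passed adjusted over the list alone), ependymal and cilia genes (8, median 0.64), the respiratory chain encoded in the nucleus (21, median 0.15), cytosolic ribosomal proteins (27, median 0.14), oligodendrocyte genes (15, median 0.16), interneuron genes (17, median 0.10, with the neuropeptide gene Npy at 0.53, SE 0.17) and microglia genes (14, median 0.13). Heat shock and unfolded protein genes were lower (16, median -0.14). In these 7 lists other than blood 0 members passed adjusted over the list alone. The camera adjusted p-values of the 8 lists, none of them called with an estimated correlation, ran from 0.000182 to 0.0403. With an estimated correlation the adjusted p-values of all lists called but the ribosomal one lay between 0.786 and 0.790, and that of the ribosomal proteins was 0.898. With 1 library left out, the heat shock call was kept in 0 of 4 fits, and each of the other 7 calls in 2 of 4. Without Y402F replicate 1 only the interneuron and oligodendrocyte lists of these 8 kept their call. In that fit the ribosomal proteins and microglia genes also turned direction.

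Among known partners and substrates of Pyk2, 0 of 33 members were called, over all genes or adjusted over the list alone (median -0.06, camera adjusted p = 0.260). Grin2b, an NMDA receptor subunit, differed by -0.46 (SE 0.21) and the adaptor gene Pxn by -0.26 (SE 0.18). Of 49 clustered protocadherins 0 were called (median -0.04, camera adjusted p = 0.538), with Pcdhac1 at 0.73 (SE 0.27) and Pcdhb11 at -0.99 (SE 0.38). Of 20 genes next to Ptk2b on chromosome 14, 0 were called (median 0.00, camera adjusted p = 0.947). Pnoc, the prepronociceptin gene, was at 0.62 (SE 0.22) and Stmn4 at -0.27 (SE 0.14). The 4 sex genes did not differ by edgeR, with Xist at -0.67 (SE 1.25) and Ddx3y at 0.09 (SE 0.92), as each group held 1 library of each pattern.

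The wild-type pairs of the 2 lines, compared within tables made the same way, differed in many genes. Of 12974 genes 1046 (8.06%) were called by limma, 632 higher and 414 lower in KO controls. Higher were the lectin gene Clec4a2 (1.93), the lipoprotein gene Apoc1 (1.90), the phosphatase gene Ptpn18 (1.93), Arhgap27 (3.57, SE 0.29), Snhg9 (3.09), the histone gene H4c8 (2.12), Tmsb15b2 (2.11), Gpr21 (2.01), Depdc5 (1.94) and Prss36 (1.82). Lower were the nuclear long noncoding RNAs Malat1 (-2.43, SE 0.29) and Meg3 (-1.87), the choroid plexus channel genes Kcnj13 (-2.04) and Kcne2 (-2.0), the immediate early gene Egr2 (-1.77), and Tnfrsf18 (-2.11), Wsb1 (-1.99), Bud23 (-1.87), Trp53i13 (-1.74) and Gpsm2 (-1.72). The limma adjusted p-values of these 20 genes ran from 0.00570 to 0.0488, and Ptk2b did not differ detectably (-0.05, SE 0.11, limma adjusted p = 0.785). Every KO control had a female and every Y402F control a male pattern, so sex and line cannot be told apart within these 4 libraries. A term for sex, estimated with the mutant libraries and added after seeing the data, gave 1283 calls, of which 654 were among the 1046. The count was 383 when only these 4 libraries were fitted, 170 without the trend, 514 without a filter, and 259, 269, 256 and 176 without KO control replicates 1 and 2 and Y402F control replicates 1 and 2.

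Nuclear genes of the respiratory chain and cytosolic ribosomal proteins were higher in the KO controls. In the respiratory chain 14 of 21 members rose (19 adjusted over the list alone, median 0.51, camera adjusted p = 3.73e-10, adjusted p = 0.499 with an estimated correlation), among them Atp5j2 (0.95, SE 0.10) and Ndufb2 (0.87, SE 0.11). Of 27 ribosomal proteins 17 rose, with 21 higher and 1 lower adjusted over the list alone (median 0.58, camera adjusted p = 2.74e-09, adjusted p = 0.499 with an estimated correlation), among them Rps14 (1.08, SE 0.16) and Rpl8 (0.80, SE 0.11). Heat shock and unfolded protein genes followed with 6 of 16 (8 adjusted over the list alone, median 0.42, camera adjusted p = 6.19e-05, adjusted p = 0.339 with an estimated correlation), including the endoplasmic reticulum chaperone gene Calr (0.58) and Sdf2l1 (1.20). In microglia genes 4 of 14 rose and 1 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.00456, adjusted p = 0.534 with an estimated correlation), with the complement gene C1qc at 0.76 and Tyrobp at 0.88. In blood 4 of 6 rose (5 adjusted over the list alone, camera adjusted p = 0.00456, adjusted p = 0.499 with an estimated correlation), with Hba-a2 at 1.02 and Hbb-bs at 0.82. Oligodendrocyte genes had 3 of 15 higher (5 adjusted over the list alone, camera adjusted p = 0.0329, adjusted p = 0.499 with an estimated correlation), with the myelin genes Mbp at 0.75 and Cnp at 0.79.

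Immediate early genes were lower in KO controls. Of 26 members 8 fell over all genes (15 lower and 1 higher adjusted over the list alone, median -0.53, camera adjusted p = 4.92e-05, adjusted p = 0.499 with an estimated correlation), among them Egr1 (-1.04, SE 0.16), Arc (-0.93, SE 0.16) and Dusp6 (-0.59, SE 0.11). In choroid plexus 6 of 8 fell (8 adjusted over the list alone, median -1.63, camera adjusted p = 2.19e-05, adjusted p = 0.499 with an estimated correlation), including Enpp2 (-1.64) and the klotho gene Kl (-1.23). The dentate granule list had 4 of 12 lower (4 lower and 1 higher adjusted over the list alone, median -0.38, camera adjusted p = 0.00456, adjusted p = 0.499 with an estimated correlation), with Npnt at -1.07 and Prox1 at -0.82. Neocortex markers had 3 of 13 lower (6 lower and 1 higher adjusted over the list alone, median -0.39, camera adjusted p = 0.0177, adjusted p = 0.499 with an estimated correlation), with Rasgrf2 at -0.62 and Etv1 at -0.71. The oligodendrocyte call was lost without KO control replicate 2 (0.162), Y402F control replicate 1 (0.0804) and Y402F control replicate 2 (0.0682). The neocortex call was lost without KO control replicate 1 (0.0763) and Y402F control replicate 2 (0.0898).

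Camera called none of 6 other lists in which at least 2 members differed, given as higher and lower members and then the same counts adjusted over the list alone (alone): astrocytes (6 and 0 of 15, alone 7 and 3), interneurons (3 and 0 of 17, alone 3 and 1), CA2 (2 and 0 of 7, alone 2 and 0), integrin and focal adhesion (2 and 0 of 23, alone 2 and 0), glucocorticoid response (2 and 0 of 14, alone 2 and 0) and cholesterol synthesis (0 and 2 of 16, alone 0 and 2).

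Among the neighbours of Ptk2b, 2 of 20 genes rose in the KO controls, also adjusted over the list alone: Ephx2, a soluble epoxide hydrolase (0.62, SE 0.14, limma adjusted p = 0.0390), and Pnoc (0.59, SE 0.14, limma adjusted p = 0.0392). Partners of Pyk2 (33 members, median -0.02) and clustered protocadherins (49, median -0.13) had 0 calls, over all genes and adjusted over the list alone. Of the 4 sex genes 0 were called over all genes and 3 were lower adjusted over the list alone, with Ddx3y at -2.54 (SE 0.88) and Xist at 1.97 (SE 1.69).

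The difference between the KO effect and the Y402F effect, each against its own controls, was called by limma for 4 genes of 12974, while 1690 had an unadjusted p under 0.05. Ptk2b was among them, with -2.52 (SE 0.15, limma adjusted p = 4.08e-04). The other 3 fall outside the naming rule and were chosen after their values were seen: the long noncoding RNA A830082N09Rik (-6.70, SE 0.24), the Y RNA gene Rny1 (-5.63, SE 0.26) and the microRNA gene Mir8104 (-4.42, SE 0.30). A830082N09Rik was at 422 ± 35.2 scaled FPKM in the KO controls and at 2.25 to 2.83 on average in the other 3 groups (n = 2 each). In the mutants, Rny1 and Mir8104 rest on 1 and on 7 or 8 expected counts in the Y402F libraries and on 0 in KO. Most of the Rny1 difference came from KO controls above Y402F controls, as KO against Y402F gave -1.74 by limma. Mir8104 was not called at a pseudocount of 0.1 (limma adjusted p = 0.118). Sex does not cancel in this difference, because both KO controls had a female and both Y402F controls a male pattern. A term for sex, added after seeing the data, raised the number of calls to 138, of which 4 were the same genes. Ptk2 differed by -0.31 (SE 0.24, limma adjusted p = 0.625).

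Immediate early genes had a more positive effect in KO than in Y402F, with 21 of 26 members positive and a median of 0.82 (camera adjusted p = 2.26e-10, adjusted p = 0.637 with an estimated correlation). Over all genes 0 were called and 14 were higher adjusted over the list alone. Egr2 (2.45, SE 0.38), Fos (2.36, SE 0.37), Egr1 (1.57, SE 0.22) and Arc (1.5, SE 0.23) had limma adjusted p-values of 0.0997 to 0.103. The median of this list was 0.30 in KO against Y402F and -0.53 in KO controls against Y402F controls. Heat shock and unfolded protein genes (16 members, median -0.60, Calr -0.62), the respiratory chain (21, median -0.43, Ndufa4 -0.61) and ribosomal proteins (27, median -0.42, Rpl38 -0.49) had a more negative effect in KO, each with a camera adjusted p of 7.83e-07 (adjusted p = 0.176, 0.637 and 0.637 with an estimated correlation). For the respiratory chain and ribosomal proteins KO itself lay above Y402F (medians 0.15 and 0.14), and the KO controls lay further above the Y402F controls (0.51 and 0.58). For heat shock genes the medians were -0.14 and 0.42. In the respiratory chain and ribosomal lists, only Y402F replicate 1 lay below both KO libraries. Mean log2(scaled FPKM + 1) of the respiratory chain was 7.36 and 7.42 in KO and 7.13 and 7.38 in Y402F. That of the ribosomal proteins was 7.96 and 8.05 in KO and 7.73 and 8.05 in Y402F. Adjusted over the list alone 7, 6 and 12 members of the heat shock, respiratory chain and ribosomal lists were lower, and 0 over all genes. Choroid plexus (8, median 1.03, Enpp2 1.11, camera adjusted p = 0.00314, adjusted p = 0.637 with an estimated correlation) and neocortex genes (13, median 0.37, Rasgrf2 0.64, camera adjusted p = 0.0379, adjusted p = 0.637 with an estimated correlation) were more positive, with 0 and 2 members higher adjusted over the list alone. The choroid plexus call was lost without Y402F replicate 1 (0.0691), and the neocortex call without 4 of the 8 libraries (KO replicate 1, 0.234; KO control replicate 1, 0.132; Y402F control replicate 1, 0.0547; Y402F control replicate 2, 0.177). Partners of Pyk2, clustered protocadherins, neighbours of Ptk2b and sex genes had 0 calls, over all genes and adjusted over each list alone (camera adjusted p = 0.713, 0.488, 0.830 and 0.261).

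Against the KO controls, 4882 of 12974 genes (37.6%) were called in KO by limma, 2160 higher and 2722 lower. Of these 1606 changed at least 2-fold. Counts of called list members are to be read against that share of all tested genes. Processing cannot be told from genotype in this comparison. After Ptk2b, immediate early genes rose together. Of 26 members 16 rose and 0 fell (17 adjusted over the list alone, median 0.69, camera adjusted p = 9.04e-07, adjusted p = 0.790 with an estimated correlation), with Egr1 at 73.6 ± 10.8 scaled FPKM in KO and 18.8 ± 0.417 in its controls (n = 2 each; log2 difference 1.91, SE 0.16), Arc at 1.93 (SE 0.16), Nr4a1 at 1.46 (SE 0.15) and Junb at 1.45 (SE 0.17). In the respiratory chain 17 of 21 members fell, also adjusted over the list alone (median -0.65, camera adjusted p = 2.95e-06, adjusted p = 0.790 with an estimated correlation), such as Uqcrq (-1.54) and Cox6b1 (-1.41). Mean log2(scaled FPKM + 1) of this list was 8.13 in both KO controls, 7.59 in both Y402F controls and 7.13 to 7.42 in the mutants. Of 49 clustered protocadherins 18 rose and 1 fell, also adjusted over the list alone (median 0.51, camera adjusted p = 3.10e-05, adjusted p = 0.790 with an estimated correlation), with Pcdhb14 at 1.29, Pcdhac2 at 0.86 and Pcdhgc4 at -3.45. Among partners of Pyk2 5 of 33 rose and 8 fell (6 and 8 adjusted over the list alone, camera adjusted p = 0.709), including the kinase gene Fyn (-1.06), the scaffold gene Dlg4 (-0.69) and Wasl (0.74). Of the neighbours of Ptk2b 4 of 20 rose and 4 fell (5 and 4 adjusted over the list alone), including Stmn4 (-0.88) and Hmbox1 (-1.04). Of the 4 sex genes 0 were called, over all genes or adjusted over the list alone.

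Camera did not call the following lists, in which at least 2 members changed in KO. With 37.6% of all tested genes called, such counts alone do not set a list apart. For these lists the members that rose and fell are given, followed by the same counts adjusted over the list alone (alone). At synapses and adhesion sites they were ionotropic glutamate receptors (5 and 1 of 21, alone 5 and 1), postsynaptic scaffold (8 and 8 of 28, alone 8 and 9) and GABA synapse (10 and 1 of 19, alone 10 and 1). Others were synaptic vesicle (9 and 1 of 26, alone 9 and 1) and integrin and focal adhesion (1 and 5 of 23, alone 1 and 5). Further ones were monoamine and acetylcholine receptors (4 and 1 of 20, alone 4 and 1). Among neurons they were pan-neuronal genes (4 and 4 of 11, alone 4 and 5), CA1 (2 and 1 of 10, alone 1 and 0) and CA2 (1 and 1 of 7, alone 1 and 1). Others were CA3 (2 and 1 of 10, alone 2 and 1), dentate granule cells (6 and 1 of 12, alone 6 and 1) and interneurons (2 and 5 of 17, alone 2 and 5). Further ones were neocortex (3 and 1 of 13, alone 4 and 1) and thalamus (3 and 0 of 11, alone 0 and 0). Among glia, vessels and neighbouring tissues they were astrocytes (4 and 5 of 15, alone 4 and 6), oligodendrocytes (4 and 4 of 15, alone 4 and 4) and oligodendrocyte precursors (2 and 0 of 10, alone 2 and 0). Others were microglia (0 and 3 of 14, alone 0 and 3), endothelium (1 and 1 of 12, alone 0 and 0) and mural cells (1 and 2 of 10, alone 0 and 2). Further ones were leptomeninges (0 and 5 of 13, alone 0 and 5), ependyma (0 and 2 of 8, alone 0 and 2) and blood (0 and 2 of 6, alone 0 and 2). Among states and housekeeping groups they were interferon response (1 and 2 of 16, alone 1 and 2), glucocorticoid response (2 and 3 of 14, alone 2 and 3) and circadian clock (4 and 2 of 16, alone 4 and 2). Others were heat shock and unfolded protein (1 and 9 of 16, alone 1 and 10), cholesterol synthesis (3 and 1 of 16, alone 3 and 1) and cytosolic ribosomal proteins (10 and 11 of 27, alone 10 and 11).

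The largest rises in KO against its controls were Npcd (7.63), Chn1os3 (5.87), Fam219aos (5.85), Tmem150b (5.39), Gdf1 (5.04), Grin1os (4.98), Slc3a1 (4.68), Gpr39 (4.65), Wdr89 (4.47) and Omd (4.36). Npcd, which overlaps the neuronal pentraxin receptor locus, was at 197 ± 6.52 scaled FPKM in KO and 214 ± 0.159 in Y402F, and listed at or near 0 in the 4 controls. The largest falls were Gstp2 (-7.34), Nbr1 (-6.47), Bc1 (-6.10), Snurf (-6.04), Tuba1c (-5.94), Hmga1b (-5.23), Chd9 (-4.72), Snhg9 (-4.53), Zbed5 (-4.50) and Ly6c2 (-4.45). The limma adjusted p-values of these 20 genes ran from 1.15e-07 to 0.00262. Without scaling 1400 genes were higher and 3329 lower, and with quantile normalization 2917 and 2211. With values scaled to the sum of each library they were 11607 and 157, where the median gene moved by 1.59. A term for sex, added after seeing the data, gave 4821 calls, of which 4235 were among the 4882. The count fell to 3116 without KO replicate 1.

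Against the Y402F controls, 4192 of 12974 genes (32.3%) were called in Y402F by limma, 1686 higher and 2506 lower. Of these 1490 changed at least 2-fold. Member counts of lists are to be read against that share, and processing cannot be told from genotype here either. Cytosolic ribosomal proteins were higher as a list, with 13 of 27 rising and 3 falling (14 and 5 adjusted over the list alone, median 0.38, camera adjusted p = 0.0487, adjusted p = 0.982 with an estimated correlation), among them Rpl10 (2.67), Rps23 (2.18) and Rpl19 (1.84). That call was lost without Y402F replicate 2 (camera adjusted p = 0.264). Clustered protocadherins again rose, 13 of 49 against 2 that fell (15 and 2 adjusted over the list alone, median 0.44, camera adjusted p = 2.82e-04, adjusted p = 0.982 with an estimated correlation), with Pcdhga11 at 1.03, Pcdhac2 at 0.72 and Pcdhgc4 at -3.87. Of 26 immediate early genes 3 rose and 1 fell (1 and 1 adjusted over the list alone, median 0.08, camera adjusted p = 0.737), including Ier5 (0.61, SE 0.13) and Egr2 (-1.52, SE 0.27), the latter lost against all 4 wild-type libraries (limma adjusted p = 0.418). Partners of Pyk2 had 5 of 33 higher and 8 lower (5 and 9 adjusted over the list alone), with Fyn at -0.68 and the ubiquitin ligase gene Cbl at -1.47. Of the neighbours of Ptk2b 4 of 20 rose and 4 fell (5 and 4 adjusted over the list alone), with Stmn4 at -0.48 and Hmbox1 at -0.95, and of the 4 sex genes 0 were called, over all genes or adjusted over the list alone.

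Camera did not call the following lists, in which at least 2 members changed in Y402F. With 32.3% of all tested genes called, such counts alone do not set a list apart. For these lists the members that rose and fell are given, followed by the same counts adjusted over the list alone (alone). At synapses and adhesion sites they were ionotropic glutamate receptors (5 and 1 of 21, alone 5 and 1), postsynaptic scaffold (6 and 7 of 28, alone 7 and 8) and GABA synapse (5 and 2 of 19, alone 7 and 2). Others were synaptic vesicle (7 and 2 of 26, alone 7 and 2) and integrin and focal adhesion (0 and 5 of 23, alone 0 and 2). Further ones were monoamine and acetylcholine receptors (3 and 0 of 20, alone 1 and 0). Among neurons they were pan-neuronal genes (2 and 2 of 11, alone 2 and 2), CA1 (1 and 3 of 10, alone 2 and 3) and CA2 (2 and 0 of 7, alone 2 and 0). Others were CA3 (4 and 0 of 10, alone 4 and 1), dentate granule cells (2 and 1 of 12, alone 2 and 1) and interneurons (0 and 4 of 17, alone 0 and 4). Further ones were neocortex (1 and 2 of 13, alone 0 and 2). Among glia, vessels and neighbouring tissues they were astrocytes (2 and 4 of 15, alone 2 and 4), oligodendrocytes (5 and 3 of 15, alone 6 and 3) and oligodendrocyte precursors (2 and 0 of 10, alone 1 and 0). Others were microglia (0 and 3 of 14, alone 0 and 3), endothelium (1 and 1 of 12, alone 1 and 1) and mural cells (1 and 1 of 10, alone 0 and 1). Further ones were leptomeninges (0 and 2 of 13, alone 0 and 2), choroid plexus (0 and 4 of 8, alone 0 and 4) and ependyma (0 and 2 of 8, alone 0 and 2). The last of these lists was blood (1 and 2 of 6, alone 2 and 2). Among states and housekeeping groups they were interferon response (1 and 3 of 16, alone 1 and 3), glucocorticoid response (0 and 3 of 14, alone 0 and 3) and circadian clock (2 and 2 of 16, alone 2 and 2). Others were heat shock and unfolded protein (2 and 3 of 16, alone 3 and 3), cholesterol synthesis (2 and 4 of 16, alone 2 and 4) and respiratory chain (0 and 11 of 21, alone 0 and 14).

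The largest rises in Y402F were Npcd (7.46), Chn1os3 (5.8), Fam219aos (5.73), Gdf1 (5.6), Tmem150b (5.19), Gpr39 (4.78), Grin1os (4.57), Slc3a1 (4.56), Cntd1 (4.49) and Mybph (4.41). The largest falls were Gstp2 (-7.00), Nbr1 (-6.31), Tuba1c (-5.20), Snurf (-5.11), Bc1 (-4.92), Chd9 (-4.88), Hmga1b (-4.66), Gas5 (-4.59), Ulk4 (-4.29) and Bud23 (-4.27), and the limma adjusted p-values of all 20 ran from 1.72e-07 to 1.10e-04. Without scaling 987 genes were higher and 3137 lower, and with quantile normalization 2724 and 2153. Scaled to the sum of each library they were 9970 and 365, where the median gene moved by 1.08. The sex term gave 3897 calls, of which 3494 were among the 4192.

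The 2 comparisons with controls shared most of their calls. Of the genes called in both (3019), 3007 had the same sign, 1173 higher and 1834 lower, where lists of these sizes drawn independently would share 281 and 526. Across genes, which are not independent replicates, the log2 differences of the 2 lines had a Pearson correlation of 0.819 and a Spearman correlation of 0.749. The comparisons share no library, but both set tables of one kind against tables of the other. On log2(scaled FPKM + 1), mutant libraries correlated with each other at 0.979 to 0.985, the controls of a line at 0.965 and 0.966, controls of different lines at 0.951 to 0.954, and mutants with controls at 0.878 to 0.894. Ptk2b and A830082N09Rik lay off this shared pattern.

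**Figure D4:**
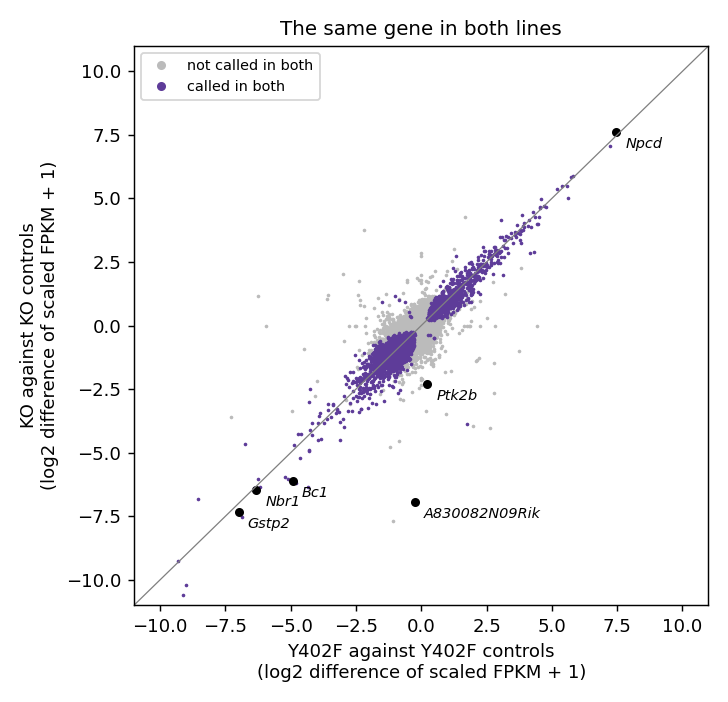
Log2 difference of scaled FPKM + 1 of each tested gene in KO against KO controls (y axis) and in Y402F against Y402F controls (x axis); purple genes were called in both, and the grey line marks equal values. Most called genes follow the line, and Ptk2b lies at -2.29 in KO and 0.22 in Y402F.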

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

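Of the tests below, those of overlapping genes and of transcript length were chosen before their results were seen; the others were chosen after.

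The effects of the 2 lines differed, by the test of the difference itself, for Ptk2b (-2.52), A830082N09Rik (-6.70), Rny1 (-5.63) and Mir8104 (-4.42), and for 6 lists with their medians: immediate early genes (0.82), choroid plexus (1.03), neocortex (0.37), heat shock and unfolded protein (-0.60), the respiratory chain (-0.43) and cytosolic ribosomal proteins (-0.42). The list differences were not called with an estimated correlation. In this test sex does not cancel, since the KO controls had a female and the Y402F controls a male pattern. The list differences may thus hold a part that comes from sex. A830082N09Rik was high in the KO controls alone, at 397 and 447 scaled FPKM against 1.89 to 2.89 in the other 6 libraries. Rny1 was listed at 13.8 in both KO controls and at 0 in both Y402F controls, and Mir8104 at 22.8 and 18.2 in the Y402F libraries and at or near 0 in the other 6.

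Many genes, 3007 by count, differed between mutants and controls in the same direction in both lines. The correlation was r = 0.819. A response to altered Pyk2 common to both alleles and a difference of processing would both give it. The 2 cannot be told apart because every mutant table is of one kind and every control table of the other. A difference of library preparation between mutants and controls would look the same and was not tested. Of 989 genes changed at least 2-fold the same way in both lines, 66.4% overlap another annotated gene, against 56.3% of the other tested genes (odds ratio 1.54, 95% interval 1.34 to 1.77), in line with counting that treats overlapping genes differently, which may account for part of them. The mean change had a Spearman correlation of 0.14 with transcript length across genes, between the bounds set beforehand for and against a length bias (0.2 and 0.05), with medians of -0.16 in the shortest 25% of genes and 0.10 in the longest. A biological part of the shared differences stays open and was not tested.

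Immediate early genes were higher in KO than in Y402F. The difference was positive within both the female and the male pair (medians 0.13 and 0.58, 18 and 24 of 26 genes positive, above the 95th percentiles of 10000 random lists at 0.07 and 0.08). Each pair sets 1 library against 1, and random lists ignore how these genes move together, so the percentiles decide little. KO and Y402F each held 1 library of each pattern, so a difference of sex alone cancels in this comparison. More dentate granule tissue in the KO dissections is argued against by the direction of the dentate granule list. Its median was -0.24, with list means of 3.65 and 3.75 in KO and 3.86 and 3.85 in Y402F. That median lay under the 5th percentile of random lists (-0.09), which decides little for the same reason. The camera call of this list was lost without KO replicate 1. The wild-type pairs differed on the immediate early list by -0.53, more than the mutants did. KO controls had a female and Y402F controls a male pattern, so sex and line cannot be told apart there. Mean log2(scaled FPKM + 1) of the list was 3.02 and 2.98 in KO controls and 3.48 and 3.46 in Y402F controls. It was 3.69 and 4.01 in KO and 3.56 and 3.40 in Y402F. Group differences unrelated to Pyk2 may thus be large enough to separate the mutants, but handling or time of collection was not tested. Loss of Pyk2 stays open, since KO exceeded its own controls by a median of 0.69 but those controls were themselves below the other wild-type pair and came from other tables.

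Choroid plexus genes were lower in KO than in Y402F. All 8 tested genes were highest in Y402F replicate 2 among the 4 mutant libraries, where Ttr and Enpp2 reached 653 and 82.1 scaled FPKM. That test was chosen after this library was seen to be high, so it restates the pattern. All 8 were also higher in both wild-type Y402F controls than in either KO control, so high values occurred without the Y402F allele. Choroid plexus tissue in some dissections would give this, but it was not told apart from line or sex. The filter on the mean over all 8 libraries favours genes high in some of them, so it partly sets these counts. Clic6 was at 1.90 in Y402F replicate 2 and 2.71 and 2.47 in the Y402F controls, against at most 0.285 elsewhere. The libraries with high Ttr (653, 1011 and 1028) all had a male pattern, while KO replicate 2, also male, had 10.2. Y402F replicate 1 did not lie above the KO libraries (median -0.12, against a 95th percentile of random lists of 0.18). This rests on 1 library, and random lists ignore how the 8 genes move together, so alone it cannot decide on the Y402F allele.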

How the results depend on the processing

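The term for sex, the relative log expression size factors, limma for KO against Y402F and the leave-one-out list tests were chosen after seeing the data. Ptk2b in KO stayed called under every setting run, between -0.49 (scaled to the sum of each library) and -2.43 (no scaling) apart from the leave-one-out fits (-2.44 to -2.15). Ptk2b in Y402F became called with quantile normalization (0.36), scaled to the sum of each library (1.42) and with the sex term (0.34), and was not called with any library left out (0.15 to 0.31).

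Scaling to the sum of each library lets Bc1 set the scale of the controls. It gave 11764 calls for KO against its controls, 10335 for Y402F against its controls, 3706 for the difference of effects and 6972 between the wild-type pairs (59 higher and 6913 lower in KO controls). It turned the sign of Ptk2 (1.29 in KO, 1.01 in Y402F), Fyn (0.74 and 0.51), Stmn4 (0.94 and 0.72) and Hmbox1 (0.67 and 0.18) against controls, of Cox6b1 (0.41), Uqcrq (0.27) and Dlg4 (1.13) in KO, and of Calr between wild-type pairs (-0.0407). Quantile normalization set Bc1, the top gene of each library's ranks in controls and mutants, to a difference of 0 in both lines. A 2-fold minimum left 1606, 1490 and 168 calls in KO, in Y402F and between wild-type pairs.

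For the difference of effects there were 7 calls without a filter, 2 at a mean of at least 5 FPKM, 2 without counting-dependent gene classes and 138 with the sex term; the causes were not tested. Between wild-type pairs there were 514 without a filter, 170 without the trend and 383 with only these groups; the sex term turned Xist to -2.89. For KO against Y402F limma called 5 genes with each of the pseudocounts 0.1, 1 and 5 and with quantile normalization, edgeR 2 with relative log expression factors and 2 without counting-dependent classes, and DESeq2 2. The causes were not tested. For these counts, scaling to the sum is the library-size setting, which called 1 gene; limma without the trend was not run there.

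With 1 library left out, calls ranged from 3116 to 3582 for KO, 2842 to 3008 for Y402F, 6 to 15 for the difference, 176 to 269 between wild-type pairs and 16 to 34 for KO against Y402F. There sex was no longer balanced: Ddx3y ranged from -5.77 to 5.88 and Xist from -7.29 to 6.87, and the lone library is assumed to vary like the other groups. Camera then called 6 (without KO replicate 2) to 10 lists for KO against Y402F, and 3 lists turned direction in a single fit, without being called there. Their camera adjusted p-values ranged from 1.48e-10 to 0.485 (ribosomal proteins, turned without Y402F replicate 1), from 9.15e-05 to 0.999 (microglia, likewise) and from 4.81e-95 to 0.707 (choroid plexus, turned without Y402F replicate 2). An estimated correlation left 0 lists in each of the 5 comparisons, and quantile normalization gave 5 in KO against its controls.

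The replicate numbers were not shown to pair the libraries: deviations of same-numbered libraries correlated at 0.20 between KO and Y402F and at -0.03 to 0.05 otherwise. With the replicate block 4 genes were called for KO against Y402F, 1 higher and 3 lower, with 612 genes at an unadjusted p under 0.05, and 1 list for Y402F against its controls. No other number of calls moved by over 1.5 times. In the mutants the replicate number coincides with sex, so the sex term gave the same 4 calls. Calls of named genes weakened most between the wild-type pairs (166 results), and 2 libraries per group limit all tests.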

Other observations

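The levels of 2 genes, chosen after their values were seen, were higher in both KO and KO control libraries than in any Y402F or Y402F control library. How many other genes share this order was not counted. Pnoc, a neighbour of Ptk2b on chromosome 14, was at 8.42 and 8.24 scaled FPKM in the KO libraries and 10.6 and 10.3 in KO controls, against 5.53 and 5.30 in Y402F and 6.64 in both Y402F controls. The histone gene H4c8 was at 4.64 ± 0.0176 and 5.71 ± 0.153 in the KO line and at 1.52 ± 0.817 and 0.544 ± 0.156 in the Y402F line (mutants, then wild types; SD, n = 2 each). Both were called between the wild-type pairs by limma, and neither in KO against Y402F by edgeR. Across all tested genes, which are not independent replicates, the limma log2 differences between the lines in mutants and in wild types correlated with r = 0.136.

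Bc1, a short cytoplasmic RNA of neurons, was at 1010410 and 980453 scaled FPKM in the KO controls, 502591 and 527099 in the Y402F controls, and 12487 to 23073 in the mutants.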
